A study of Mus musculus with 12 samples.

How the data were processed

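RNA was measured in 12 libraries of NK cells sorted from mouse pancreatic tumours on day 21, 3 each from mice given control IgG, cGAMP, anti-IL-35 antibody or both. RNA was extracted with RNeasy (NEBNext Ultra libraries). The deposited values are raw read counts per gene, which the authors made, per the labels, with STAR 2.7.7a, SAMtools 1.15 and featureCounts on build mm10. The version of featureCounts, the annotation, the strand setting, the treatment of reads that map to several places and the gate of the sort were not given in the sources used here. The deposited table held 27179 Entrez gene IDs with gene symbols. All 12 of its columns were mapped to a group and replicate. No symbol was given for 1049 IDs, which took 0.251% of counts and were kept under their ID. RefSeq annotation of build mm10 gave coordinates for 25275 IDs.

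Molecular identifiers were not described in the sources used here, and counting intervals and floors cover counting error only. A planned rule would have counted libraries of a group that differed by no more than counting noise as 1 sample, to find a library deposited more than once. It cannot tell separate preparations of one pool from separate animals. Within groups the chi-square over degrees of freedom of pairs of libraries was 3.24 to 11.7, above the value of 1 under counting noise, and the 12 libraries were each counted once. A group with no counts was set at a floor of 3 counts over the group, and intervals of ratios were exact at 95%.

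Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by group with a minimum count of 10, which left 14182 genes, and libraries were scaled by TMM. A single quasi-likelihood fit with robust dispersion held the 4 groups and all 12 libraries, with 8 residual degrees of freedom, a common biological coefficient of variation of 0.0958 and 37.4 prior degrees of freedom. The 6 comparisons were each treatment against IgG, the combination against each single treatment, and the interaction of both treatments. Quasi-likelihood tests were adjusted by Benjamini-Hochberg within a comparison, and genes with an adjusted p under 0.05 were called. All adjusted p-values of genes come from this test unless DESeq2 is named.

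Before the data were examined, 30 gene lists with 623 genes (577 measured) were fixed from general knowledge. They held 19 lists of NK cell biology, signalling and metabolism and 11 of markers of other cell types. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over 30 lists per comparison. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were also run. Camera called 12, 11, 11, 13, 9 and 11 lists in the order of comparisons above. Of these 10, 8, 7, 9, 8 and 10 held with an estimated correlation (smallest adjusted p 4.27e-08 to 3.31e-05).

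Genes were named by rules fixed before the data were examined. The largest rule took, among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries of the groups, the 10 largest changes in each direction for comparisons with IgG and the 5 largest for the other comparisons. For the interaction the rule of overlap was not applied. Symbols that are only clone or locus numbers, ribosomal protein genes and mitochondrial genes were passed over for naming. Up to 4 members with the smallest p of each list could be named, 1 listed gene is not reported here, and 20 fixed genes were always named. A second set passing over immunoglobulin V segments was chosen after values were seen, and not all of its genes are named.

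The effects of each treatment without and with the other were compared by Pearson and Spearman correlation across genes, with a jackknife over the 12 libraries. Overlap between the comparisons with IgG was set beside the overlap of independent lists and beside 20 simulations of unchanged groups. These drew all 12 libraries, the controls included, from a common level of each gene. The fit was tested on simulated data made from the deposited counts. Of the genes raised or lowered 2-fold, 81.8% were recovered for cGAMP against IgG and 71.2% for the interaction. At 1.3-fold these shares were 32.8% and 10.4%, so many changes of that size stay undetected, and false calls made up 4.31% and 5.95% of calls.

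Alternatives set beforehand were RLE size factors, library totals alone, DESeq2 1.42.0, no filter on low counts, a stricter filter of 1 CPM in 6 libraries, a fit of only the groups compared, a block for replicate number, and leaving out each library. Alternatives chosen after seeing the data were scaling on 9 NK receptor transcripts, and a fit without 218 immunoglobulin and 163 other-cell-list genes, which tested 13764 genes after filtering anew.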

Results

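RNA was sequenced from natural killer (NK) cells sorted on day 21 from tumours of a mouse pancreatic cancer model. NK cells are innate lymphocytes that kill target cells with perforin and granzymes. The 12 libraries formed 4 groups of 3, given IgG (control), cGAMP, an antibody that blocks IL-35, or both. cGAMP is a cyclic dinucleotide that activates STING, an adaptor of the cytosolic DNA sensing pathway, and was injected intravenously at 10 µg on 4 occasions. IL-35 is a cytokine made of the Ebi3 and Il12a subunits, and the antibody was given intraperitoneally at 200 µg on 3 occasions. Both courses started on day 8 and were repeated every 3 days. Library totals ran from 12811353 to 22217766 assigned reads. Values after a symbol are log2 fold changes ± SE, and levels are TMM-scaled CPM (read counts per library size), given as mean ± SD with n = 3. The labels did not say that the 3 libraries of a group came from separate animals. So p-values of genes measure only the spread between these libraries, which may be technical. Camera p-values take genes as units under a preset correlation.

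Transcripts of other cell types were present in every group and moved with treatment. Summed over 16 measured markers, neutrophil transcripts stood at 4946 ± 106, 11310 ± 105, 21460 ± 668 and 19440 ± 58.8 CPM with IgG, cGAMP, anti-IL-35 and the combination. B cell markers summed to 16570 ± 184, 17450 ± 290, 7693 ± 38.4 and 17680 ± 143 CPM in the same order. Dendritic cell markers, most of their level being MHC class II genes, fell from 7416 ± 95.1 CPM with IgG to 6172 ± 44.2, 5057 ± 117 and 6263 ± 175 with cGAMP, anti-IL-35 and the combination. The 25 activating NK receptor and adaptor genes summed to 5299 ± 34.2, 5874 ± 108, 6069 ± 57.3 and 5637 ± 27.1 CPM with IgG, cGAMP, anti-IL-35 and the combination. Yet 10 members were lower and 5 higher with the combination than with IgG. Shares of counts that can reflect RNA quality moved too: mitochondrial transcripts took 6.10 ± 0.107% with IgG, 8.19 ± 0.46% with cGAMP, 5.86 ± 0.397% with anti-IL-35 and 6.44 ± 0.378% with the combination, and ribosomal protein genes 6.12 ± 0.0353%, 5.72 ± 0.248%, 4.96 ± 0.176% and 5.10 ± 0.0664%.

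**Figure D1:**
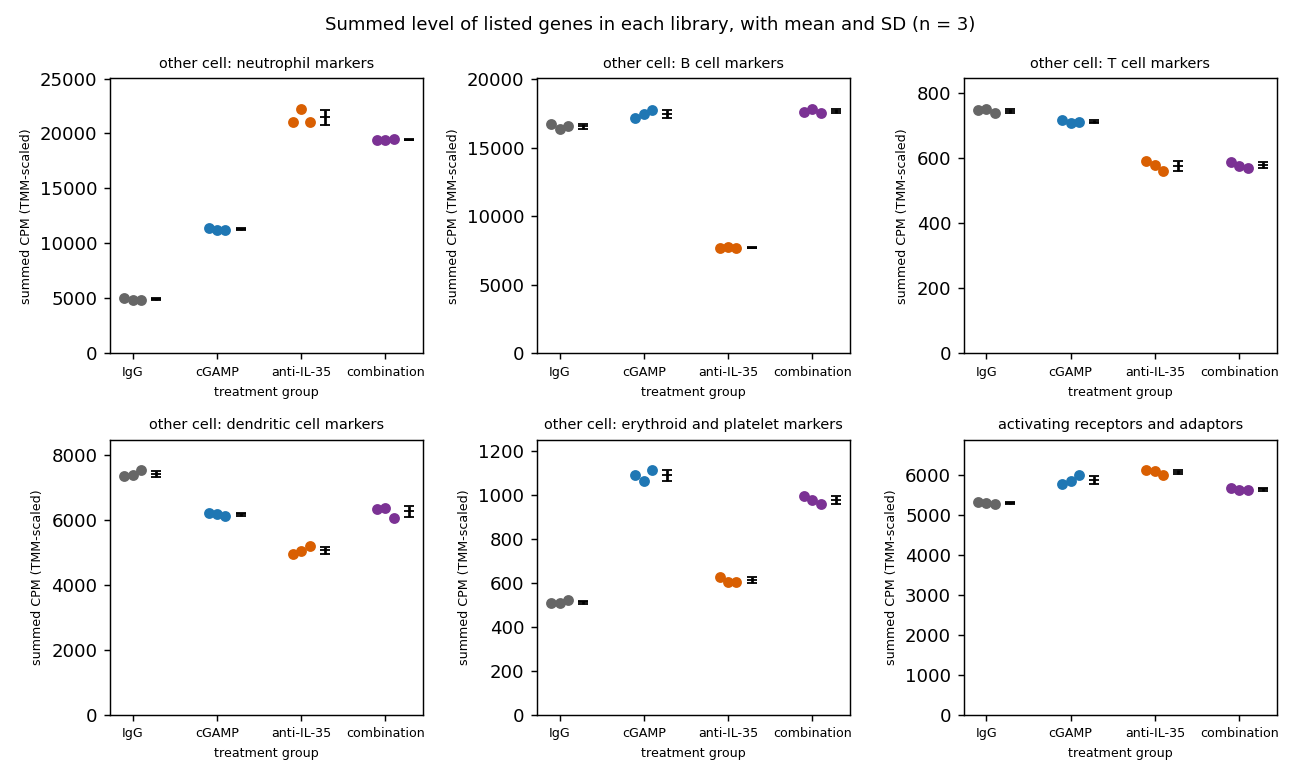
Each panel plots the summed TMM-scaled CPM of a gene list (vertical axis) in each of the 12 libraries by treatment group, with the group mean and SD (n = 3) beside the points. Neutrophil markers rise from 4946 CPM in the IgG group to 21460 CPM with anti-IL-35.

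Immunoglobulin V segments, the variable exons that B cells join into antibody genes, differed between groups and little between the libraries of a group. Across the 193 V segments tested, log2 levels correlated at r of 0.967 to 0.989 between libraries of the same group and at 0.776 to 0.861 between libraries of different groups. For other genes the ranges were 0.973 to 0.987 and 0.96 to 0.983. These correlations are across genes, which are not independent replicates. Counts of libraries of a group differed by more than counting noise (chi-square per degree of freedom of 3.24 to 11.7), as separate preparations from one pool would too.

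**Figure D2:**
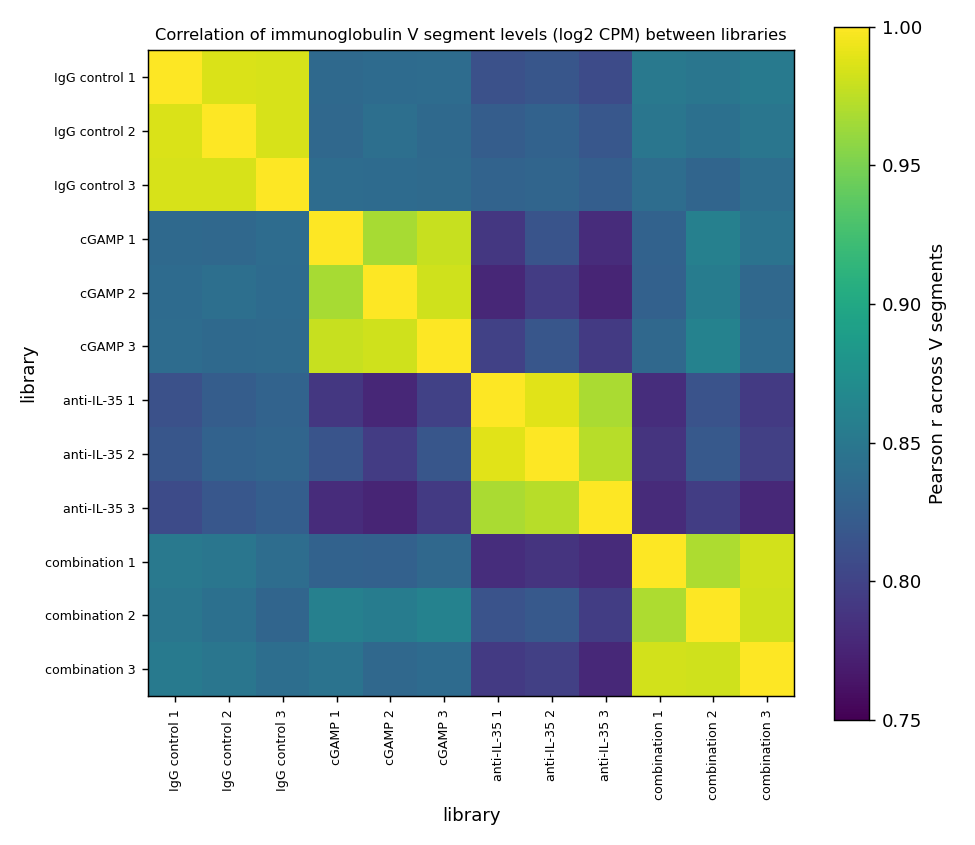
The colour of each square gives Pearson r of log2 CPM across immunoglobulin V segments for a pair of libraries, with the 12 libraries in group order on both axes. The blocks of 3 libraries along the diagonal lie at 0.967 or above, and squares outside these blocks lie at 0.861 or below.

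Scaling set the balance of higher and lower calls. TMM left the median log2 fold change of all 14182 tested genes near 0 in each comparison. With library totals alone, with no correction for composition, this median moved to -0.09 for cGAMP, -0.15 for anti-IL-35 and -0.18 for the combination against IgG. With libraries scaled on 9 NK receptor transcripts, a setting chosen after seeing the data, it moved to -0.12, -0.01 and 0.19 in the same order, and to 0.35 for the combination against cGAMP. In the order of the comparisons below, this setting ended or turned 11, 5, 12, 16, 10 and 12 of the 71, 79, 71, 56, 42 and 45 calls of genes named with a fold change, and added 3, 0, 4, 8, 6 and 8. It holds NK receptors near 0 by construction and shifts other genes, so a receptor call that ends under it is not evidence against the change. List tests compare a list with all other genes and so are relative to this shift.

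**Figure D3:**
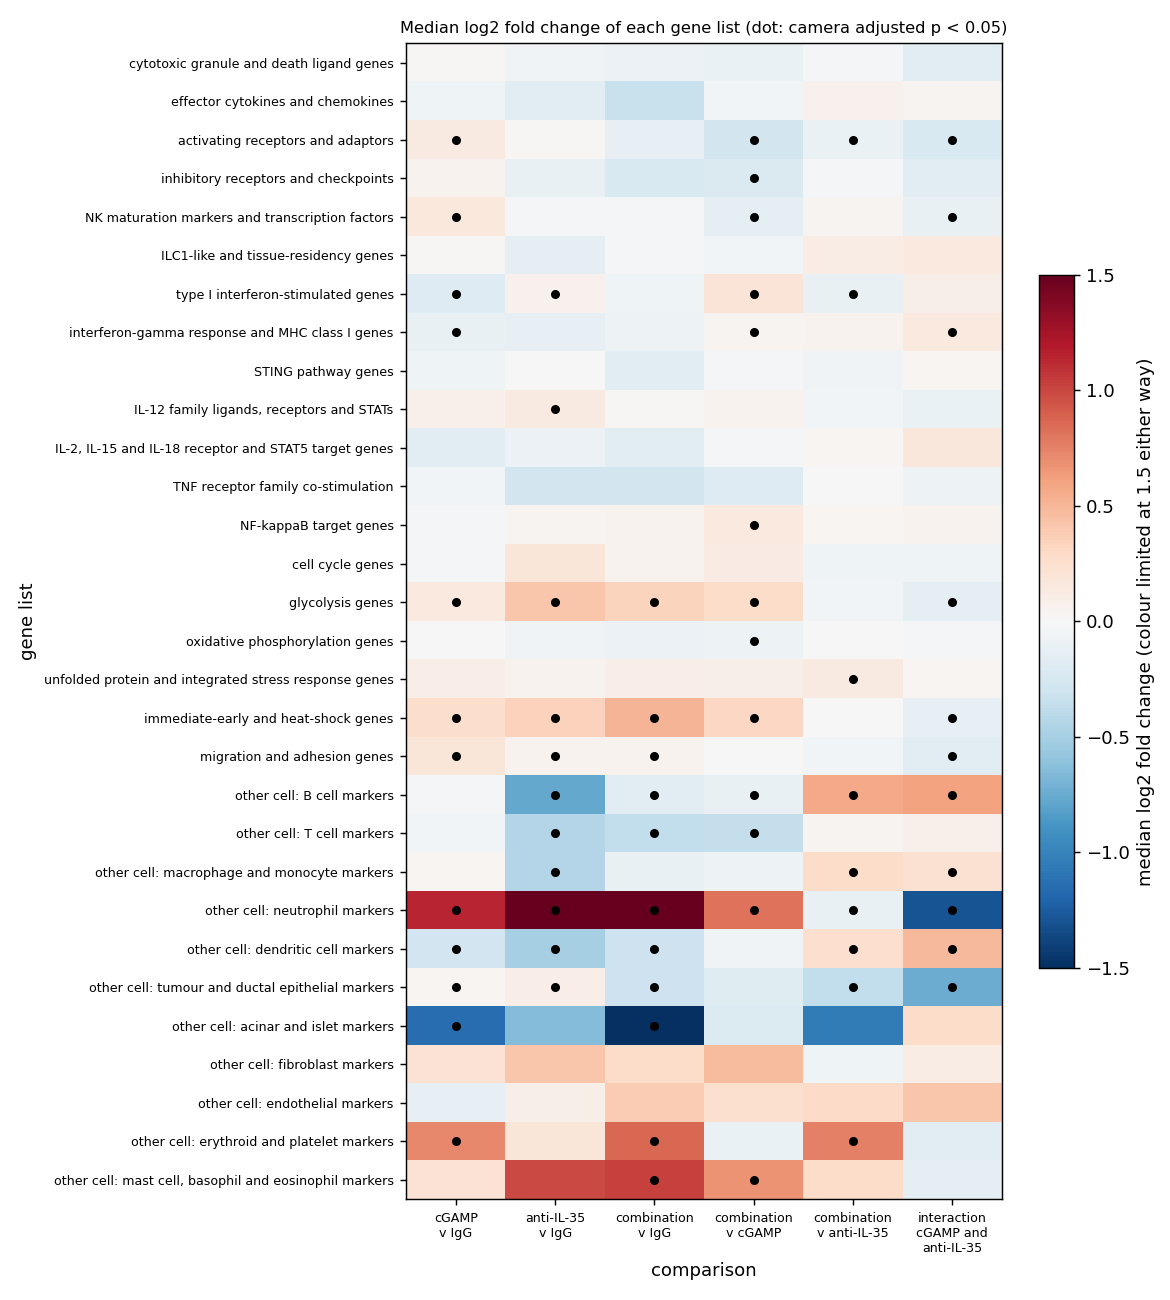
The colour of each square gives the median log2 fold change of a gene list (vertical axis) in a comparison (horizontal axis), limited at 1.5 either way, and a dot marks a camera adjusted p under 0.05. The neutrophil list has its largest medians against IgG, 2.13 with anti-IL-35 and 1.99 with the combination.

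The first comparison asked what the STING agonist changed on its own. Neutrophil transcripts rose in the cGAMP libraries: Mpo, the myeloperoxidase of primary granules (gene 17523, chromosome 11, 87793784 to 87804412), went from 57.3 ± 5.87 to 196 ± 5.79 CPM. Interferon-stimulated genes fell by a small amount, while glycolysis, immediate-early and migration genes rose. Arg1 (arginase 1) and Spp1 (osteopontin), both abundant in tumour macrophages, fell from 57.0 ± 1.37 to 14.9 ± 2.21 CPM and from 28.6 ± 2.13 to 7.74 ± 2.48 CPM. Among the NK effector genes, Prf1 (perforin, gene 18646, chromosome 10, 61297751 to 61304684) rose from 639 ± 2.12 to 728 ± 16.3 CPM, whereas Gzmb (granzyme B) and Ifng (interferon gamma) did not pass the test, Gzmb being called lower with library totals alone (-0.198, adjusted p = 0.00135).

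edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1834 of 14182 genes, 1329 higher and 505 lower, of which 104 and 90 changed at least 2-fold. Library totals alone gave 601 higher and 1277 lower calls. V segments supplied 120 of the calls.

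All 16 measured neutrophil markers were higher, and all 16 also when adjusted over the list alone (median 1.14, camera adjusted p = 9.38e-190). Examples were Ngp (1.34 ± 0.03, adjusted p = 2.38e-34), Ltf (1.29 ± 0.03) and S100a9 (1.21 ± 0.03), which encode granule and calcium-binding proteins of neutrophils. The rule for named genes took the granule protease Elane (1.71 ± 0.09) beside Mpo (1.78 ± 0.06). Erythroid and platelet markers rose as well, with 7 of 12 members higher and 7 adjusted over the list alone (median 0.72, adjusted p = 1.05e-16), among them the globins Hba-a2 (1.31 ± 0.04) and Hba-a1 (1.26 ± 0.05) and the haem synthesis enzyme Alas2 (1.12 ± 0.17). Dendritic cell markers fell in 7 of 18 members and rose in none (adjusted over the list alone, 4 higher and 10 lower). Their median was -0.28 (adjusted p = 0.000647), led by the MHC class II genes H2-Eb1 (-0.31 ± 0.04), H2-Ab1 (-0.32 ± 0.04) and Cd74 (-0.23 ± 0.03). In the tumour and ductal list, 3 of 15 members rose (4 over the list alone, adjusted p = 0.00286), among them Lcn2 (1.24 ± 0.04) and S100a6 (0.42 ± 0.05). Lcn2 and S100a6 are also expressed by neutrophils and other myeloid cells, and the keratins of the list were not called. Acinar and islet markers were lower as a list (median -1.14, adjusted p = 0.0301, 0.0793 with an estimated correlation). Of 8 members 1 was called, also over the list alone, the elastase gene Cela2a (-3.02 ± 0.85).

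Type I interferon-stimulated genes were lower in 9 and higher in 1 of 39 measured members (adjusted over the list alone, 14 and 2). Their median was -0.19 (adjusted p = 0.000221). The antiviral gene Oasl2 (0.42 ± 0.06) rose, and Ifi27l2a (-0.56 ± 0.08), Slfn5 (-0.38 ± 0.06) and Irf7 (-0.47 ± 0.08), the transcription factor that amplifies type I interferon, fell. Interferon-gamma response and MHC class I genes were lower in 8 of 32 members and higher in none (adjusted over the list alone, 10 and 1). Their median was -0.11 (adjusted p = 0.000143), including Nlrc5 (-0.40 ± 0.06), the transactivator of MHC class I genes, the chemokine Cxcl9 (-1.0 ± 0.16) and Socs1 (-0.62 ± 0.12). The 13 measured STING pathway genes did not move as a list (2 higher and 1 lower, 2 and 2 over the list alone, adjusted p = 0.545), and Sting1, listed as Tmem173, gave -0.06 ± 0.07.

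Glycolysis genes rose in 7 of 21 members (8 over the list alone). Their median was 0.15 (adjusted p = 0.000369), with Slc2a3 (0.66 ± 0.05) and Slc16a3 (0.70 ± 0.06), carriers of glucose and lactate, and Pfkfb4 (0.48 ± 0.07). Immediate-early and heat-shock genes rose in 14 of 28 members with 1 lower (18 and 5 over the list alone). Their median was 0.26 (adjusted p = 9.6e-12); Dusp1 (1.02 ± 0.05), Fos (0.77 ± 0.05), Zfp36 (0.52 ± 0.04) and Hsph1 (0.63 ± 0.06) led. Migration and adhesion genes rose in 13 of 21 members with 1 lower (13 and 1 over the list alone). Their median was 0.18 (adjusted p = 0.000143), among them Cd44 (0.51 ± 0.04), Cxcr4 (0.44 ± 0.05) and Ccr1 (0.51 ± 0.06). Slc2a3, Fos, Cxcr4 and Ccr1 are also expressed by neutrophils, whose marker list had a median of 1.14 in the same comparison.

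In the NK lists, 12 of 25 activating receptor and adaptor genes rose and none fell (13 over the list alone). Their median was 0.13 (adjusted p = 0.023, adjusted p = 0.0516 with an estimated correlation), including Klra9 (0.41 ± 0.05), Cd2 (0.29 ± 0.06), Tyrobp (0.22 ± 0.04) and Fcgr3 (0.23 ± 0.05). Tyrobp and Fcgr3 are shared with myeloid cells. NK maturation markers and transcription factors rose in 11 of 26 members (16 over the list alone). Their median was 0.16 (adjusted p = 0.00253), such as Itgam (0.22 ± 0.04), also a myeloid integrin, Spn (0.23 ± 0.04), Ets1 (0.19 ± 0.04) and S1pr5 (0.26 ± 0.05). Among the fixed genes, Ebi3 (0.82 ± 0.16), a subunit of IL-35 and IL-27, Prf1 (0.19 ± 0.04, adjusted p = 0.000405), Il12rb2 (0.32 ± 0.07), Klrk1 (0.15 ± 0.05) and Tbx21 (0.17 ± 0.05) rose. The other fixed genes were not called: Gzmb (-0.09 ± 0.04), Ifng (0.02 ± 0.12), Ncr1 (0.03 ± 0.04), Eomes (0.15 ± 0.05), Il2ra (0.05 ± 0.19), Pdcd1 (-0.16 ± 0.27), Tigit (-0.10 ± 0.12), Lag3 (-0.002 ± 0.10), Havcr2 (-0.10 ± 0.12), Il12a (-0.98 ± 0.54), Il6st (0.06 ± 0.08), Il27ra (-0.17 ± 0.08), Isg15 (-0.20 ± 0.14) and Mki67 (-0.10 ± 0.06). Both NK list calls ended with library totals alone (adjusted p = 0.27 for activating receptors and 0.0971 for maturation) and with NK receptor scaling (0.45 and 0.156), which also ended the glycolysis (0.0773) and acinar calls (0.129) and those of Prf1, Il12rb2, Klrk1, Tbx21, Cd2, Tyrobp, Fcgr3, Itgam, Spn, Ets1 and S1pr5. It added calls of Gzmb, Il27ra and Mki67, all lower, and of the IL-2, B cell and macrophage lists. Library totals alone ended those of Prf1 (0.212), Klrk1 (0.626), Tbx21 (0.571), Ets1 (0.188), Fcgr3 (0.115), S1pr5 (0.0648), Tyrobp (0.0833) and the acinar list (0.14). They added calls for Il27ra (0.00895) and Mki67 (0.0063), both lower, and the IL-2 (0.0334), B cell (0.0103) and macrophage lists (0.0215). A fit of only the groups compared added Gzmb (0.0414) and Il27ra (0.0491), and the stricter filter (0.0482) or leaving out cGAMP replicate 3 (0.0169) added Eomes. Cela2a was lost with DESeq2 (0.0856) and without IgG control replicate 3 (0.0537) or cGAMP replicate 2 (0.064). Leaving out cGAMP replicate 3 ended the activating receptor call (0.0561) and that of Klrk1 (0.0662), and leaving out IgG control replicate 1 those of the acinar list (0.0646) and Tbx21 (0.129). Klrk1 was also lost without IgG control replicate 2 (0.0556) or 3 (0.0814) or cGAMP replicate 2 (0.0809). Tbx21 was lost too without IgG control replicate 2 (0.15) or cGAMP replicate 1 (0.178) or 2 (0.17), with DESeq2 (0.0582) and with a replicate block (0.0548). With no filter on low counts Klrk1 (0.0587) and Tbx21 (0.0581) were lost.

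The remaining lists did not pass. Cytotoxic granule genes had 5 members higher and 1 lower of 18 (5 and 1 over the list alone, adjusted p = 0.495). Effector cytokines had 4 higher and 1 lower of 16 (adjusted p = 0.837). Adjusted p was 0.18 for inhibitory receptors and checkpoints, 0.901 for ILC1-like and residency genes, 0.312 for the IL-12 family, 0.272 for IL-2, IL-15 and IL-18 receptor genes, 0.718 for TNF receptor family co-stimulation, 0.604 for NF-kappaB targets, 0.551 for cell cycle genes, 0.74 for oxidative phosphorylation and 0.72 for the unfolded protein response. Adjusted p was 0.258 for B cell, 0.18 for T cell, 0.261 for macrophage, 0.356 for fibroblast, 0.643 for endothelial and 0.452 for mast cell, basophil and eosinophil markers. Median, mean and test differed in sign for the residency, co-stimulation, cell cycle, oxidative phosphorylation, macrophage and fibroblast lists.

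The rule for named genes, which asks for the largest changes with no overlap between the libraries of the groups, mostly took immunoglobulin genes. Ighe, the constant region of IgE (gene 380792, chromosome 12, 113269263 to 113273248), rose from 1.48 ± 0.765 to 10.4 ± 1.59 CPM, and the V segments Igkv3-4 (2.29 ± 0.05), Ighv6-6 (2.05 ± 0.07), Ighv1-31 (1.96 ± 0.30), Ighv1-20 (1.78 ± 0.20), Igkv4-61 (1.71 ± 0.12) and Ighv9-1 (1.44 ± 0.18) rose with it. Ighv1-43 fell from 606 counts over the IgG libraries to 2 counts over the cGAMP libraries, a 284-fold lower level whose ratio has an exact 95% counting interval of 0.000426 to 0.0128. Also lower were Ighv1-84 (-5.68 ± 0.25), Ighv1-36 (-4.98 ± 0.47), Igkv8-21 (-3.83 ± 0.16), Ighv2-6-8 (-2.89 ± 0.35), Ighv1-4 (-2.35 ± 0.16), Ighv12-3 (-2.14 ± 0.25) and Igkv4-57-1 (-2.13 ± 0.08). V segments resemble each other, so the reads of a single segment are uncertain. The other genes taken by the rule were Ncam1 (1.85 ± 0.26), a neural cell adhesion molecule, Dmbt1 (-3.89 ± 0.47), a scavenger receptor of epithelia, and Ptprv (-2.34 ± 0.26). Passing over V segments, a choice made after values were seen, the rule also took Ankrd22 (1.43 ± 0.23), Cstdc4 (1.43 ± 0.15), Il1bos (1.42 ± 0.25) (an antisense gene, uncertain as the strand of the library was not given), Hbb-b1 (1.40 ± 0.06), the granule protease Prtn3 (1.38 ± 0.08) and Olfml2b (1.38 ± 0.15) among the higher genes. It took Dab2 (-1.67 ± 0.26), Mmp12 (-1.45 ± 0.28), Arg1 (-1.92 ± 0.12) and Spp1 (-1.90 ± 0.19) among the lower ones. It further took 4 pancreatic amylase copies, for example Amy2a2 (-2.0 ± 0.27), which are nearly identical, so that the level of each is uncertain.

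The second comparison asked what blocking IL-35 changed on its own. Neutrophil transcripts rose further than with cGAMP, and B cell, T cell and dendritic cell markers fell. Most macrophage markers fell, although their sum rose from 7024 ± 38.9 CPM with IgG to 7565 ± 50.5 CPM. S100a9, a calcium-binding protein abundant in neutrophils (gene 20202, chromosome 3, 90692630 to 90695721), went from 1240.0 ± 24.3 to 5587 ± 288 CPM, and Ighm, the constant region of IgM (gene 16019, chromosome 12, 113418826 to 113422730), from 7673 ± 64.3 to 2480.0 ± 33.5 CPM. Glycolysis and immediate-early genes rose, and a subset of antiviral genes rose with them: Oasl2 went from 83.4 ± 1.58 to 303 ± 15.0 CPM. Of the IL-35 subunits, Ebi3 rose from 9.39 ± 1.70 to 21.6 ± 2.46 CPM and Il12a fell from 2.41 ± 0.333 to 0.535 ± 0.296 CPM.

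edgeR's quasi-likelihood test called 3542 genes, 2220 higher and 1322 lower, with 467 and 181 at least 2-fold changed, and 148 of the calls were V segments. Scaling on library totals alone gave 1472 higher and 3125 lower calls.

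All 16 neutrophil markers rose (all 16 over the list alone). Their median was 2.13 (adjusted p = 1.14e-195, 8.55e-08 with an estimated correlation), with Ngp (2.10 ± 0.03, adjusted p = 1.33e-42), Ltf (2.25 ± 0.04) and the gelatinase Mmp9 (2.26 ± 0.04). B cell markers fell in 19 and rose in 1 of 21 (20 and 1 over the list alone). Their median was -0.76 (adjusted p = 5.35e-33), with Ighm (-1.63 ± 0.03), Igkc (-0.82 ± 0.03), the complement receptor Cr2 (-1.16 ± 0.06) and Iglc2 (-1.27 ± 0.07). T cell markers fell in 11 of 17 (13 over the list alone). Their median was -0.44 (adjusted p = 0.000857), including Cd4 (-0.81 ± 0.10), Trbc2 (-0.41 ± 0.06) and Cd3g (-0.65 ± 0.10). Dendritic cell markers fell in 9 of 18 (13 over the list alone). Their median was -0.50 (adjusted p = 1.72e-06), led again by Cd74 (-0.51 ± 0.03) and H2-Eb1 (-0.60 ± 0.04). Macrophage and monocyte markers fell in 14 and rose in 4 of 21 (15 and 4 over the list alone). Their median was -0.43 (adjusted p = 0.0114); Arg1 (-1.55 ± 0.11) fell, while Chil3 (1.32 ± 0.04), Lyz2 (0.36 ± 0.03) and Cd14 (0.80 ± 0.07), which neutrophils also express, rose. The tumour and ductal list had 5 of 15 members higher and none lower (5 over the list alone, adjusted p = 0.000627), among them again Lcn2 (2.20 ± 0.04) and S100a6 (0.87 ± 0.05), with the adhesion molecule Cdh1 (1.03 ± 0.21).

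Glycolysis genes rose in 16 of 21 members with 1 lower (17 and 1 over the list alone). Their median was 0.42 (adjusted p = 1.11e-13), including Slc16a3 (1.80 ± 0.06), Slc2a3 (1.25 ± 0.05), Pfkfb4 (1.48 ± 0.07) and the pyruvate kinase Pkm (0.71 ± 0.04). Immediate-early and heat-shock genes rose in 20 of 28 with 3 lower (20 and 5 over the list alone). Their median was 0.34 (adjusted p = 9.09e-20), among them Dusp1 (2.23 ± 0.05), Fos (1.63 ± 0.05), Zfp36 (1.40 ± 0.04) and Junb (1.47 ± 0.04). Migration and adhesion genes rose in 9 and fell in 5 of 21 (10 and 7 over the list alone). Their median was 0.05 (adjusted p = 0.0121, adjusted p = 0.0858 with an estimated correlation), with Ccr1 (1.69 ± 0.06), Cd44 (0.87 ± 0.04), Cxcr4 (0.87 ± 0.05) and Selplg (0.69 ± 0.04) higher. These members are shared with neutrophils, whose list median was 2.13.

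Type I interferon-stimulated genes rose in 14 and fell in 6 of 39 members (16 and 9 over the list alone). Their median was 0.07 (adjusted p = 0.0209, adjusted p = 0.1 with an estimated correlation). The oligoadenylate synthetase family genes Oasl2 (1.86 ± 0.06), Oas3 (1.25 ± 0.06) and Oas2 (1.27 ± 0.10) and Trim30a (0.61 ± 0.06) led. The IL-12 family list rose in 6 and fell in 3 of 16 (6 and 3 over the list alone). Their median was 0.14 (adjusted p = 0.0271, adjusted p = 0.1 with an estimated correlation); the higher members were led by Socs3 (1.71 ± 0.05), Il6ra (0.63 ± 0.06), Stat3 (0.46 ± 0.04) and Ebi3 (1.21 ± 0.16), of which Socs3, Il6ra and Stat3 act in cytokine signalling of many cells, neutrophils included. Interferon-gamma response genes did not pass as a list (4 higher and 11 lower of 32, 4 and 17 over the list alone, adjusted p = 0.191).

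In the NK lists, activating receptors had 7 members higher and 5 lower of 25 (8 and 5 over the list alone, adjusted p = 0.504). The higher members with the smallest p were Fcgr3 (0.85 ± 0.05), Syk (0.48 ± 0.04), Tyrobp (0.42 ± 0.04) and Fcer1g (0.37 ± 0.04), which myeloid cells also express. Inhibitory receptors had 4 higher and 6 lower of 21 (adjusted p = 0.914): Entpd1 (0.98 ± 0.05) and Lilrb4a (1.09 ± 0.06), an inhibitory receptor of myeloid cells, were higher, and Btla (-0.70 ± 0.08) and Lag3 (-0.59 ± 0.10, adjusted p = 9.32e-06) lower. Cytotoxic granule genes had 4 higher and 3 lower of 18 (adjusted p = 0.82), and effector cytokines 3 and 4 of 16 (adjusted p = 0.847). Cell cycle genes rose in 11 of 40 members, although the list did not pass (adjusted p = 0.208). Residency genes had 2 higher and 8 lower of 22 (adjusted p = 0.199), and mast cell, basophil and eosinophil markers 6 higher and 2 lower of 10 (adjusted p = 0.0595). Median, mean and test differed in sign for the cytotoxic, effector, maturation, STING, co-stimulation, unfolded protein, fibroblast and endothelial lists.

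Of the fixed genes, Ebi3 (1.21 ± 0.16), Mki67 (0.29 ± 0.06), Eomes (0.20 ± 0.05) and Prf1 (0.13 ± 0.04) were higher, and Il12a (-2.15 ± 0.56), Lag3 (-0.59 ± 0.10), Il2ra (-0.66 ± 0.19), Il6st (-0.28 ± 0.08), Pdcd1 (-0.89 ± 0.27), Tmem173 (-0.22 ± 0.07), Il27ra (-0.24 ± 0.08), Tigit (-0.35 ± 0.12) and Ncr1 (-0.12 ± 0.04) lower. The rest were not called: Ifng (-0.03 ± 0.12), Gzmb (-0.07 ± 0.04), Klrk1 (0.03 ± 0.05), Tbx21 (0.13 ± 0.05), Havcr2 (-0.27 ± 0.12), Il12rb2 (0.15 ± 0.07) and Isg15 (0.32 ± 0.14). With library totals alone Prf1 moved to -0.002 (adjusted p = 0.982), Eomes lost its call (0.285), and the calls of the migration (0.0857) and IL-12 family lists (0.0773) ended. Gzmb (0.000518) and Havcr2 (0.0101) were then called lower, and the interferon-gamma (0.0203), oxidative phosphorylation (0.0493) and mast cell lists (0.0252) gained calls. With NK receptor scaling the IL-12 family call ended (0.058), as did those of Prf1 (0.108), Ncr1 (0.242), Il27ra (0.0968), Tigit (0.0565) and Tmem173 (0.0567), and the mast cell list gained a call (0.0257). Ncr1 was lost with only the groups compared (0.0545) or a replicate block (0.0634), and Prf1 with no filter (0.0831). Il12rb2 gained a call without IgG control replicate 2 (0.037) and Tbx21 without anti-IL-35 replicate 1 (0.0271). Leaving out a library ended several calls. Without IgG control replicate 1 adjusted p was 0.213 for Ncr1, 0.113 for Pdcd1, 0.0679 for Tigit, 0.0992 for Il27ra and 0.158 for Tmem173. Without IgG control replicate 3 it was 0.0813 for Ncr1 and 0.136 for Tigit, and without anti-IL-35 replicate 1 it was 0.164 for Prf1 and 0.0521 for the type I interferon list. Without anti-IL-35 replicate 2 it was 0.0808 for Ncr1, 0.0806 for Tigit and 0.08 for Il27ra. Without anti-IL-35 replicate 3 it was 0.15 for Ncr1, 0.0619 for Il2ra, 0.0558 for Pdcd1, 0.0653 for Tigit and 0.0839 for Tmem173.

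By size, the rule took Igkv4-62 (3.59 ± 0.19), the chemoattractants and receptors of myeloid cells Prok2 (3.14 ± 0.27) and Cxcr1 (2.55 ± 0.22), the endothelial lipase Lipg (2.58 ± 0.15), Scrg1 (3.02 ± 0.44), Chil1 (2.48 ± 0.06), Ccdc80 (2.42 ± 0.23), Nlrp12 (2.41 ± 0.07), Chac1 (2.37 ± 0.26), which degrades glutathione, and Mpo (2.37 ± 0.06) among the higher genes. Among the lower genes were V segments only. Ighv1-43 had 606 counts over the IgG libraries and 0 over the anti-IL-35 libraries, at least 243-fold lower against a floor of 3 counts over the group. The others were Ighv1-36 (-6.26 ± 0.52), Ighv1-84 (-5.47 ± 0.24), Igkv14-130 (-4.09 ± 0.38), Igkv8-16 (-3.47 ± 0.37), Igkv4-57-1 (-3.34 ± 0.08), Ighv1-20 (-3.14 ± 0.26), Igkv1-99 (-3.09 ± 0.22), Igkv4-70 (-3.02 ± 0.14) and Igkv4-63 (-2.92 ± 0.12). Passing over V segments, it took Lrg1 (2.36 ± 0.05) among the higher and the IgG3 constant region Ighg3 (-2.20 ± 0.05), Ighm (-1.63 ± 0.03) and Arg1 (-1.55 ± 0.11) among the lower genes.

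The third comparison set the combination against the IgG control. Neutrophil, erythroid and mast cell transcripts rose, T cell and dendritic cell transcripts fell, and most called B cell markers fell while their sum rose. Mpo went from 57.3 ± 5.87 to 341 ± 22.9 CPM, and Hdc, the histidine decarboxylase of granulocytes (gene 15186, chromosome 2, 126593659 to 126624025), from 76.5 ± 3.53 to 399.6 ± 11.0 CPM. The NK receptor genes Ncr1 (NKp46, gene 17086, chromosome 7, 4337715 to 4345184) and Klrk1 (NKG2D, gene 27007, chromosome 6, 129610323 to 129623903) fell, from 419 ± 13.1 to 346 ± 7.20 CPM and from 549.7 ± 5.38 to 480.4 ± 11.7 CPM. Dusp1, an immediate-early phosphatase, rose from 112 ± 2.09 to 492 ± 20.8 CPM.

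edgeR's quasi-likelihood test called 3288 genes, 2224 higher and 1064 lower, with 437 and 97 at least 2-fold changed, and 121 of the calls were V segments. The split was 1360 higher and 3370 lower with library totals alone, and 95.8% of 4620 calls were higher with NK receptor scaling.

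All 16 neutrophil markers rose (all 16 over the list alone). Their median was 1.99 (adjusted p = 1.2e-224, 4.27e-08 with an estimated correlation), with Ngp (1.99 ± 0.03), S100a9 (1.99 ± 0.03) and Ltf (2.07 ± 0.04) at the smallest p. Erythroid and platelet markers rose in 7 of 12 (7 over the list alone). Their median was 0.87 (adjusted p = 1.76e-05), with Hba-a2 (1.17 ± 0.04), Alas2 (1.06 ± 0.17) and the platelet integrin Itga2b (1.06 ± 0.19). Mast cell, basophil and eosinophil markers rose in 8 of 10 (8 over the list alone). Their median was 1.02 (adjusted p = 0.00312), including the eosinophil lectin Siglecf (1.38 ± 0.14) and the basophil and mast cell proteases Mcpt8 (1.29 ± 0.13) and Cpa3 (1.5 ± 0.20). T cell markers fell in 13 of 17 (13 over the list alone). Their median was -0.37 (adjusted p = 0.000434), with Trbc1 (-0.48 ± 0.07), Trbc2 (-0.40 ± 0.06) and Cd4 (-0.57 ± 0.10), and dendritic cell markers in 10 of 18 (10 over the list alone). Their median was -0.31 (adjusted p = 0.00401), with H2-Eb1 (-0.34 ± 0.04) and H2-Aa (-0.35 ± 0.04). B cell markers were lower in 10 and higher in 2 of 21 (11 and 2 over the list alone). Their median was -0.16 (adjusted p = 0.00822, 0.167 with an estimated correlation): Cd22 (-0.43 ± 0.06), Cr2 (-0.36 ± 0.06) and Iglc2 (-0.39 ± 0.06) fell and Ighm (0.19 ± 0.03) rose. In the tumour and ductal list 4 members rose and 2 fell of 15 (the same counts over the list alone). Its median was -0.31 and mean -0.22, while the test pointed up (adjusted p = 0.0338, 0.0936 with an estimated correlation), with Lcn2 (2.01 ± 0.04) and S100a6 (0.76 ± 0.05) among those that rose. Acinar and islet markers were lower (median -2.16, adjusted p = 0.0338, 0.0969 with an estimated correlation), 2 of 8 over all genes and 7 over the list alone, with Ctrb1 (-2.69 ± 0.81) and Cela2a (-2.47 ± 0.80).

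Immediate-early and heat-shock genes rose in 18 and fell in 3 of 28 (19 and 3 over the list alone). Their median was 0.51 (adjusted p = 6e-24), with Dusp1 (2.14 ± 0.05), Fos (1.28 ± 0.05) and Zfp36 (1.11 ± 0.04). Glycolysis genes rose in 16 of 21 with 1 lower (16 and 2 over the list alone). Their median was 0.34 (adjusted p = 3.05e-13), with Slc16a3 (1.88 ± 0.06), Pfkfb4 (1.26 ± 0.07) and Pkm (0.66 ± 0.04). Migration genes rose in 9 and fell in 4 of 21 (the same counts over the list alone). Their median was 0.06 (adjusted p = 0.00822, adjusted p = 0.0779 with an estimated correlation), with Ccr1 (1.39 ± 0.06), Cxcr4 (1.09 ± 0.05) and Cd44 (0.83 ± 0.04). The neutrophil median beside these lists was 1.99. Type I interferon-stimulated genes did not pass as a list (10 higher and 6 lower of 39, 12 and 8 over the list alone, adjusted p = 0.528), although Oasl2 (1.52 ± 0.06), Oas3 (0.97 ± 0.06) and Rsad2 (0.93 ± 0.11) rose. Unfolded protein response genes had 7 higher and 1 lower of 18 (adjusted p = 0.187).

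Activating receptors had 5 members higher and 10 lower of 25 (5 and 12 over the list alone, adjusted p = 0.572), the higher members led by Fcgr3 (0.82 ± 0.05), Syk (0.51 ± 0.04) and Tyrobp (0.39 ± 0.04). Inhibitory receptors had 5 and 7 of 21 (the same counts over the list alone, adjusted p = 0.603), with Klra7 (-0.40 ± 0.06) and Klra3 (-0.45 ± 0.09) lower and Entpd1 (1.0 ± 0.05) higher. Of the fixed genes, Ebi3 (1.05 ± 0.16), Mki67 (0.32 ± 0.06) and Il12rb2 (0.24 ± 0.07) rose and Ncr1 (-0.27 ± 0.04, adjusted p = 3.34e-06), Klrk1 (-0.19 ± 0.05), Eomes (-0.16 ± 0.05), Lag3 (-0.48 ± 0.10), Tigit (-0.43 ± 0.12), Il27ra (-0.26 ± 0.08) and Tmem173 (-0.22 ± 0.07) fell. The other fixed genes were not called: Ifng (-0.31 ± 0.12), Gzmb (-0.01 ± 0.04), Prf1 (0.08 ± 0.04), Tbx21 (0.08 ± 0.05), Il2ra (-0.39 ± 0.19), Pdcd1 (-0.48 ± 0.27), Havcr2 (-0.23 ± 0.12), Il12a (-0.46 ± 0.52), Il6st (-0.04 ± 0.08) and Isg15 (0.34 ± 0.14). With NK receptor scaling Klrk1 stood at 0.017 and Eomes at 0.053, and Ncr1 (adjusted p = 0.492), Lag3 (0.0566), Tigit (0.218), Il27ra (0.781), Tmem173 (0.96), Cr2, Iglc2, H2-Aa, H2-Eb1, Trbc2, the B cell list (0.291) and the tumour list (0.449) lost their calls. Prf1, Tbx21, Isg15 and Gzmb were then called higher, and the IL-12 family, NF-kappaB and unfolded protein lists gained calls. Library totals alone ended the calls of Il12rb2 (0.338), Ighm (0.334) and the migration (0.131) and acinar lists (0.132). Ifng was called lower with RLE (0.0486), library totals alone (0.00246), DESeq2 (0.0252) and only the groups compared (0.0444). Library totals alone also added Gzmb (0.00326), Havcr2 (0.0125) and Il2ra (0.0232), all lower, and the interferon-gamma (0.0456) and oxidative phosphorylation lists (0.0081). Cela2a was lost with DESeq2 (0.117) and under 4 left-out libraries (0.0658 to 0.0868), and Ctrb1 without IgG control replicate 2 (0.145) or combination replicate 3 (0.0817). The IL-12 family gained a call without IgG control replicate 3 (0.0375) or combination replicate 3 (0.039). Calls also ended without IgG control replicate 1 (adjusted p = 0.0581 for Eomes, 0.0994 for Il12rb2, 0.0706 for Il27ra, 0.182 for Tmem173 and 0.0516 for the acinar list). The same held without IgG control replicate 2 (0.0558 for the tumour list) or 3 (0.0873 for Eomes, 0.0558 for Tigit and 0.0588 for Tmem173). Calls were also lost without combination replicate 1 (0.219 for Tmem173) or combination replicate 2 (0.107 for Eomes, 0.086 for Tigit and 0.0699 for Il12rb2).

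The rule took the V segments a kappa V segment with gene ID 692182 (4.86 ± 0.54), Ighv1-66 (2.63 ± 0.15), Ighv5-15 (2.60 ± 0.43), Igkv3-4 (2.49 ± 0.05) and Ighv3-4 (2.40 ± 0.41) and, from granulocytes and their precursors, Mpo (2.57 ± 0.06), Prss57 (2.47 ± 0.29), Hdc (2.38 ± 0.05) and Elane (2.33 ± 0.09) among the higher genes, with the transcription factor Snai1 (2.30 ± 0.33). Lower genes were Ighv1-84 (-3.77 ± 0.21), Ighv1-43 (-3.73 ± 0.39), Igkv4-63 (-2.78 ± 0.12), Ighv12-3 (-2.67 ± 0.26), Igkv4-57-1 (-2.35 ± 0.08), Dmbt1 (-3.25 ± 0.43) and the amylase copies, for example Amy2a2 (-2.18 ± 0.27). Passing over V segments it also took Chac1 (2.27 ± 0.26) and the protease Ctsg (2.26 ± 0.13) among the higher genes and Ptprv (-1.88 ± 0.24) and Mmp12 (-1.59 ± 0.28) among the lower. Median, mean and test differed in sign for the effector, maturation, type I interferon, co-stimulation, macrophage and fibroblast lists.

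The fourth comparison asked what the antibody added in cGAMP-treated mice. NK receptor transcripts were lower with the combination than with cGAMP, while interferon-stimulated, glycolysis and immediate-early genes and neutrophil markers were higher. Klrk1 stood at 480.4 ± 11.7 CPM with the combination and 611 ± 14.4 CPM with cGAMP, and Ncr1 at 346 ± 7.20 and 428 ± 23.9 CPM. Oasl2 rose from 112 ± 4.18 to 240.2 ± 10.6 CPM. The secreted mucin Muc5ac (gene 17833, chromosome 7, 141788958 to 141819227) fell from 6.82 ± 0.594 to 0.149 ± 0.257 CPM.

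edgeR's quasi-likelihood test called 2102 genes, 1417 higher and 685 lower, 139 and 54 of them at least 2-fold, and 116 of the calls were V segments. With library totals alone the split was 1198 and 1063, and with NK receptor scaling 98.9% of 7138 calls were higher.

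Activating receptors fell in 13 and rose in 3 of 25 members (15 and 5 over the list alone). Their median was -0.27 (adjusted p = 0.000674). Klrb1c (-0.35 ± 0.04) (NK1.1), Klrk1 (-0.35 ± 0.05, adjusted p = 5.1e-08), Klra9 (-0.45 ± 0.05) and Ncr1 (-0.31 ± 0.04, adjusted p = 6.19e-07) fell, and Fcgr3 (0.59 ± 0.05) and Syk (0.37 ± 0.04), shared with myeloid cells, rose. Inhibitory receptors fell in 7 and rose in 2 of 21 (10 and 3 over the list alone). Their median was -0.22 (adjusted p = 0.0125, adjusted p = 0.21 with an estimated correlation), with Klra7 (-0.45 ± 0.07), Klrc1 (-0.41 ± 0.06) and Lag3 (-0.48 ± 0.10) lower and Lilrb4a (0.57 ± 0.06) higher. NK maturation genes fell in 11 and rose in 2 of 26 (11 and 2 over the list alone). Their median was -0.14 (adjusted p = 0.00627), with Id2 (-0.36 ± 0.05) and Eomes (-0.30 ± 0.05), transcription factors of the NK lineage, lower and Itgam (0.39 ± 0.04) and Nfil3 (0.60 ± 0.08) higher. Cytotoxic granule genes did not pass as a list (3 higher and 5 lower of 18, 3 and 6 over the list alone, adjusted p = 0.365), with Ctsw (-0.31 ± 0.05) and Gzma (-0.24 ± 0.04) lower. With NK receptor scaling, which fixes such receptors, none of these NK lists passed (adjusted p = 0.799 for activating receptors, 0.41 for inhibitory receptors and 0.879, with the sign turned, for maturation), and every receptor named here as lower lost its call, as did Id2, Eomes, Ctsw and Gzma. The remaining fixed genes were Mki67 (0.42 ± 0.06) and Isg15 (0.54 ± 0.14), both higher, and, not called, Ifng (-0.33 ± 0.12), Gzmb (0.07 ± 0.04), Prf1 (-0.11 ± 0.04), Tbx21 (-0.09 ± 0.05), Il2ra (-0.44 ± 0.19), Pdcd1 (-0.32 ± 0.27), Tigit (-0.33 ± 0.12), Havcr2 (-0.13 ± 0.12), Ebi3 (0.23 ± 0.15), Il12a (0.52 ± 0.54), Il12rb2 (-0.08 ± 0.07), Il6st (-0.10 ± 0.08), Il27ra (-0.09 ± 0.08) and Tmem173 (-0.16 ± 0.07). That scaling called Gzmb, Prf1, Tbx21, Ebi3, Il12rb2, Il6st, Il27ra and Tmem173 higher, and 6 further lists, IL-12 family, cell cycle, unfolded protein, migration, macrophage and acinar. Prf1 was called lower with RLE (adjusted p = 0.0374), library totals alone (0.00411), DESeq2 (0.0169) and only the groups compared (0.0188). Library totals alone called Ifng (0.0287), Tigit (0.0318) and Tmem173 (0.0465) lower, and DESeq2 Ifng (0.0262) and Tigit (0.0495). Calls were gained by Tigit without combination replicate 1 (0.0198), Tmem173 without combination replicate 2 (0.0493) and the IL-12 family without combination replicate 3 (0.0457).

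Type I interferon-stimulated genes rose in 18 of 39 members with 1 lower (20 and 1 over the list alone). Their median was 0.19 (adjusted p = 4.49e-07), with Oasl2 (1.10 ± 0.05), Oas3 (0.82 ± 0.06), Oas2 (0.91 ± 0.10) and Rsad2 (0.83 ± 0.11). Interferon-gamma response and MHC class I genes rose in 10 of 32 (11 over the list alone). Their median was 0.04 (adjusted p = 0.0323, adjusted p = 0.21 with an estimated correlation), with Gbp2 (0.60 ± 0.06), H2-D1 (0.23 ± 0.04) and Cxcl9 (0.86 ± 0.16), and the call ended with library totals alone (adjusted p = 0.112). NF-kappaB targets rose in 6 of 18 (7 over the list alone). Their median was 0.14 (adjusted p = 0.00523, adjusted p = 0.0499 with an estimated correlation), led by Tnfaip2 (0.83 ± 0.05), Bcl3 (0.55 ± 0.07) and Birc3 (0.30 ± 0.06). Glycolysis genes rose in 14 of 21 (14 over the list alone with 1 lower). Their median was 0.28 (adjusted p = 4.73e-13), with Slc16a3 (1.18 ± 0.06) and Pfkfb4 (0.78 ± 0.06), and immediate-early and heat-shock genes in 21 of 28 with 2 lower (22 and 3 over the list alone). Their median was 0.31 (adjusted p = 6.45e-17), with Dusp1 (1.12 ± 0.04), Zfp36 (0.59 ± 0.04) and Hsph1 (0.63 ± 0.05). Oxidative phosphorylation genes were lower as a list (median -0.07, adjusted p = 0.0283, adjusted p = 0.315 with an estimated correlation) with 1 of 25 members called and 1 over the list alone, the complex III gene Uqcrq (-0.40 ± 0.09). That list call ended without cGAMP replicate 1 (adjusted p = 0.0781) or 2 (0.074) and turned with NK receptor scaling (0.879), where Uqcrq lost its call.

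All 16 neutrophil markers rose (all 16 over the list alone). Their median was 0.81 (adjusted p = 7.61e-96), with Hdc (1.3 ± 0.05) and Csf3r (0.93 ± 0.04), and mast cell, basophil and eosinophil markers rose in 6 of 10 (6 over the list alone with 1 lower). Their median was 0.67 (adjusted p = 0.000252), with Mcpt8 (1.36 ± 0.13) and Siglecf (1.18 ± 0.14). T cell markers fell in 10 of 17 (12 over the list alone). Their median was -0.35 (adjusted p = 0.000167), with Trbc2 (-0.35 ± 0.06) and Trdc (-0.42 ± 0.10). B cell markers fell in 5 of 21 with 1 higher (7 and 1 over the list alone). Their median was -0.11 (adjusted p = 0.00769, adjusted p = 0.164 with an estimated correlation), with Iglc2 (-0.48 ± 0.06) and Ms4a1 (-0.34 ± 0.06). With NK receptor scaling the B cell list turned (adjusted p = 0.825), and Trbc2, Trdc, Iglc2 and Ms4a1 lost their calls.

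The rule took the V segments Ighv1-56 (4.99 ± 0.41), Ighv1-4 (3.28 ± 0.16), Ighv5-15 (2.99 ± 0.45), a kappa V segment with gene ID 692182 (2.86 ± 0.45) and Ighv1-66 (2.77 ± 0.15) as higher, and Igkv7-33 (-5.70 ± 0.56), Muc5ac (-5.47 ± 0.57), Ighe (-4.34 ± 0.40), Igkv4-63 (-3.26 ± 0.12) and Ighv1-20 (-2.94 ± 0.21) as lower. Passing over V segments it added the mast cell and basophil protease Prss34 (1.69 ± 0.10), Snai1 (1.61 ± 0.32) and Chac1 (1.55 ± 0.24) among the higher genes and the chemokine receptor Ccr9 (-1.01 ± 0.26) among the lower. Median, mean and test differed in sign for the effector, IL-2, migration, macrophage, tumour and erythroid lists.

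The fifth comparison asked what cGAMP added in antibody-treated mice. B cell transcripts were higher with the combination than with anti-IL-35 alone: Ighm stood at 8753 ± 117 against 2480.0 ± 33.5 CPM, and Ighg3 (gene 380795, chromosome 12, 113357442 to 113361232) at 348 ± 5.62 against 56.8 ± 3.03 CPM. Macrophage, dendritic cell and erythroid markers and unfolded protein response genes were higher too. NK activating receptors and type I interferon-stimulated genes were lower.

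edgeR's quasi-likelihood test called 829 genes, 521 higher and 308 lower, 109 and 35 of them at least 2-fold. V segments made up 147 of them, and without immunoglobulin genes and the genes of the other-cell lists 529 genes were called. Library totals alone gave 452 higher and 448 lower, and NK receptor scaling 2952 calls, 97.6% of them higher.

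B cell markers rose in 19 of 21 members (20 over the list alone). Their median was 0.57 (adjusted p = 6.41e-75), with Ighm (1.82 ± 0.03, adjusted p = 7.89e-43), Igkc (0.92 ± 0.03) and the J chain Jchain (0.73 ± 0.04). Macrophage markers rose in 11 of 21 (15 over the list alone). Their median was 0.28 (adjusted p = 9.91e-10), with the mannose receptor Mrc1 (0.44 ± 0.05), Apoe (0.32 ± 0.04) and Arg1 (0.87 ± 0.11). Dendritic cell markers rose in 6 of 18 (9 over the list alone). Their median was 0.26 (camera adjusted p = 0.000179), with Cd74 (0.34 ± 0.03) and H2-Ab1 (0.31 ± 0.04), beside a B cell median of 0.57. Erythroid markers rose in 4 of 12 (5 over the list alone with 1 lower). Their median was 0.76 (adjusted p = 1.01e-09), with Hba-a2 (0.88 ± 0.04) and Slc4a1 (1.21 ± 0.19). Neutrophil markers were lower in 6 and higher in 1 of 16 (6 and 1 over the list alone). Their median was -0.11 (adjusted p = 0.0222, adjusted p = 0.154 with an estimated correlation), with Csf3r (-0.35 ± 0.04) and S100a9 (-0.18 ± 0.03) lower. The tumour and ductal list was lower in 3 of 15 (4 over the list alone). Their median was -0.37 (adjusted p = 0.00511): Lcn2 (-0.20 ± 0.04) and the keratins Krt8 (-1.51 ± 0.33) and Krt7 (-1.40 ± 0.37).

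Unfolded protein and integrated stress response genes rose in 9 of 18 (the same count over the list alone). Their median was 0.14 (adjusted p = 0.00224). The members with the smallest p, Pdia4 (0.45 ± 0.05), Pdia6 (0.36 ± 0.05), Hsp90b1 (0.25 ± 0.04) and Hspa5 (0.18 ± 0.04), encode chaperones of the endoplasmic reticulum, which antibody-secreting cells hold in quantity, and the B cell median beside them was 0.57. Type I interferon-stimulated genes fell in 8 of 39 and rose in none (12 and 1 over the list alone). Their median was -0.11 (adjusted p = 0.00268), including Oasl2 (-0.34 ± 0.05), Ifit3 (-0.87 ± 0.15) and Trim30a (-0.29 ± 0.06). Activating receptors fell in 6 of 25 (9 over the list alone). Their median was -0.10 (adjusted p = 0.00293), including Klrb1c (-0.28 ± 0.04), Klrk1 (-0.22 ± 0.05, adjusted p = 0.000672) and Klrc2 (-0.33 ± 0.08).

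Of the fixed genes, Eomes (-0.36 ± 0.05), Klrk1 (-0.22 ± 0.05) and Ncr1 (-0.15 ± 0.04) fell. Not called were Ifng (-0.28 ± 0.12), Gzmb (0.06 ± 0.04), Prf1 (-0.05 ± 0.04), Tbx21 (-0.05 ± 0.05), Il2ra (0.27 ± 0.19), Pdcd1 (0.41 ± 0.28), Tigit (-0.07 ± 0.12), Lag3 (0.11 ± 0.10), Havcr2 (0.04 ± 0.12), Ebi3 (-0.15 ± 0.15), Il12a (1.68 ± 0.57), Il12rb2 (0.10 ± 0.07), Il6st (0.24 ± 0.08), Il27ra (-0.02 ± 0.08), Tmem173 (0.004 ± 0.07), Isg15 (0.02 ± 0.13) and Mki67 (0.04 ± 0.05). With NK receptor scaling the activating receptor (adjusted p = 0.506), type I interferon (0.0639) and neutrophil lists (0.981), Klrk1 (0.816), Eomes (0.113), Klrb1c, Klrc2, Oasl2, Trim30a, Csf3r and Lcn2 lost their calls, and Ncr1 and S100a9 stood at 0.042 and 0.014. Gzmb, Il12a, Il12rb2, Il6st, Lag3 and Mki67 were then called higher, and the residency, interferon-gamma, NF-kappaB and acinar lists gained calls. The neutrophil list was also lost without anti-IL-35 replicate 2 (0.0621). Ncr1 was lost without anti-IL-35 replicate 1 (0.0965) or 2 (0.0852) or combination replicate 1 (0.122) or 2 (0.12), and with only the groups compared (0.0845). Krt7 was lost without anti-IL-35 replicate 2 (0.0585) or combination replicate 1 (0.102), and Klrc2 without anti-IL-35 replicate 1 (0.0557) or combination replicate 1 (0.0616). Il12a was called higher with DESeq2 (0.0131), the stricter filter (0.0361) and without anti-IL-35 replicate 2 (0.0393), and Il6st without combination replicate 2 (0.0385). Ggt1 was lost without anti-IL-35 replicate 1 (0.0923) or 2 (0.102) or combination replicate 1 (0.211) or 3 (0.0933).

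The rule took V segments only among the higher genes: Ighv1-31 (5.45 ± 0.42), a kappa V segment with gene ID 692182 (4.60 ± 0.51), Igkv14-130 (4.54 ± 0.38), Ighv5-15 (4.14 ± 0.48) and Ighv1-56, which had 577 counts over the combination libraries and 0 over the anti-IL-35 libraries, at least 210-fold higher against a floor of 3 counts. The lower genes were Igkv4-62 (-4.16 ± 0.20), Ighv1-11 (-3.13 ± 0.26), Ighv5-6 (-2.37 ± 0.14), Igkv4-90 (-2.27 ± 0.28) and Ptprv (-2.26 ± 0.24). Passing over V segments it added Ighg3 (2.61 ± 0.05) and Ighj1 (1.69 ± 0.28) as higher and the aspartic protease Ctse (-1.95 ± 0.07), Pard6g (-1.85 ± 0.39), Prok2 (-1.25 ± 0.24) and Ggt1 (-1.08 ± 0.31) as lower. Median, mean and test differed in sign for the effector, maturation, IL-12, IL-2, co-stimulation, immediate-early, migration and fibroblast lists.

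The interaction tested whether the combination departed from the sum of the single effects on the log2 scale, so a positive value means a combination level above that sum. Neutrophil markers, glycolysis, immediate-early and migration genes and NK activating receptors lay below the sum. B cell, macrophage and dendritic cell markers and interferon-gamma response genes lay above it. Arg1 gave 2.79 ± 0.16 (adjusted p = 3.7e-19): its level was 57.0 ± 1.37 CPM with IgG, 14.9 ± 2.21 with cGAMP, 19.4 ± 0.651 with anti-IL-35 and 35.3 ± 4.53 with the combination.

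edgeR's quasi-likelihood test called 1475 genes, 514 positive and 961 negative, with 175 and 144 at least 2-fold, and 131 of the calls were V segments. The split was 759 positive and 584 negative with library totals alone, and NK receptor scaling gave 3835 calls, 94.4% of them positive.

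All 16 neutrophil markers were negative (all 16 over the list alone). Their median was -1.3 (adjusted p = 3.19e-126), with Ngp (-1.45 ± 0.04) and Ltf (-1.47 ± 0.05). Beside them, immediate-early and heat-shock genes were negative in 12 and positive in 2 of 28 (12 and 3 over the list alone). Their median was -0.12 (adjusted p = 3.48e-07), with Dusp1 (-1.12 ± 0.06), Fos (-1.11 ± 0.06) and Junb (-0.90 ± 0.06). Glycolysis genes were negative in 7 of 21 (9 over the list alone). Their median was -0.13 (adjusted p = 0.00017), with Slc2a3 (-0.80 ± 0.07) and Slc16a3 (-0.62 ± 0.08), and migration genes in 11 with 1 positive of 21 (11 and 2 over the list alone). Their median was -0.17 (adjusted p = 0.0025), with Cd44 (-0.55 ± 0.06) and Ccr1 (-0.81 ± 0.08). The tumour and ductal list was negative in 4 of 15 (6 over the list alone). Their median was -0.74 (adjusted p = 2.13e-05), with Lcn2 (-1.44 ± 0.05), S100a6 (-0.53 ± 0.07) and Krt8 (-1.47 ± 0.46) among the negative members.

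B cell markers were positive in 19 of 21 (20 over the list alone with 1 negative). Their median was 0.60 (adjusted p = 1.05e-39), with Ighm (1.64 ± 0.04) and Jchain (0.83 ± 0.06). Macrophage markers were positive in 10 and negative in 1 of 21 (11 and 1 over the list alone). Their median was 0.22 (adjusted p = 4.62e-07), with Spp1 (2.56 ± 0.26) positive and Chil3 (-0.74 ± 0.06) negative, and dendritic cell markers positive in 7 and negative in 1 of 18 (9 and 1 over the list alone). Their median was 0.49 (adjusted p = 3.35e-07), with Cd74 (0.57 ± 0.04) and H2-Ab1 (0.63 ± 0.06). Interferon-gamma response and MHC class I genes were positive in 8 of 32 (10 over the list alone). Their median was 0.14 (adjusted p = 0.000129), with Nlrc5 (0.52 ± 0.08) and the chemokines Cxcl10 (1.98 ± 0.35) and Cxcl9 (1.22 ± 0.23). Type I interferon-stimulated genes did not pass (adjusted p = 0.562).

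Activating receptors were negative in 12 of 25 (13 over the list alone). Their median was -0.23 (adjusted p = 0.000129), with Klrb1c (-0.44 ± 0.06), Klra9 (-0.47 ± 0.07), Klrk1 (-0.38 ± 0.07, adjusted p = 2.08e-05) and Cd2 (-0.46 ± 0.09). Maturation genes were negative in 8 and positive in 1 of 26 (11 and 1 over the list alone). Their median was -0.11 (adjusted p = 0.0331, adjusted p = 0.0898 with an estimated correlation), with Eomes (-0.51 ± 0.07) and S1pr5 (-0.41 ± 0.07) negative and Irf8 (0.34 ± 0.06) positive. Of the other fixed genes, Prf1 (-0.23 ± 0.06), Ncr1 (-0.19 ± 0.06) and Ebi3 (-0.97 ± 0.22) were negative and Il12a (2.66 ± 0.78) positive. Not called were Ifng (-0.30 ± 0.17), Gzmb (0.14 ± 0.06), Tbx21 (-0.22 ± 0.08), Il2ra (0.22 ± 0.27), Pdcd1 (0.57 ± 0.39), Tigit (0.03 ± 0.17), Lag3 (0.11 ± 0.15), Havcr2 (0.14 ± 0.17), Il12rb2 (-0.22 ± 0.10), Il6st (0.18 ± 0.12), Il27ra (0.15 ± 0.11), Tmem173 (0.07 ± 0.10), Isg15 (0.22 ± 0.19) and Mki67 (0.13 ± 0.08). With NK receptor scaling the activating receptor (adjusted p = 0.339), glycolysis (0.44), immediate-early (0.0723) and migration lists (0.848), Klrk1 (0.787), Eomes (0.232), Klrb1c, Klra9, Cd2, S1pr5, Cd44, Slc16a3 and S100a6 lost their calls, the maturation list turned (0.956), and Prf1 and Ncr1 stood at 0.102 and 0.153. Gzmb, Havcr2, Il27ra, Il6st, Isg15, Lag3, Mki67 and Tmem173 then became positive calls, and the IL-2, NF-kappaB and unfolded protein lists gained calls. With library totals alone the maturation list (0.165), Prf1 (0.0834) and Ncr1 (0.394) were lost. Ncr1 lost its call under 8 of the 12 left-out libraries, the adjusted p lying highest without anti-IL-35 replicate 1 (0.222). Ncr1 was lost as well with no filter (0.131), a replicate block (0.0788) or without immunoglobulin and other-cell-list genes (0.0667). Krt8 lost its call under 7 of the 12 (0.0551 to 0.0882) and with NK receptor scaling (0.0575). Library totals alone added Gzmb (0.0125) and the unfolded protein list (0.036). Tbx21 gained a call without cGAMP replicate 3 (0.00996), anti-IL-35 replicate 1 (0.0149) or combination replicate 1 (0.0409). Without anti-IL-35 replicate 3 the inhibitory receptor (0.0144) and erythroid lists (0.035) gained calls, the latter also without cGAMP replicate 2 (0.047). The maturation list lost its call without anti-IL-35 replicate 3 (0.0751), and Il12a without IgG control replicate 3 (0.0563) or combination replicate 1 (0.0558).

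Among the positive values the rule took Ighv1-43 and Ighv1-56, which had 0 counts with anti-IL-35, and Ighv1-36 (9.79 ± 0.71), Ighv1-84 (7.38 ± 0.36) and Igkv14-130 (4.79 ± 0.48). Negative were Ighe (-5.58 ± 0.54), Igkv4-62 (-5.03 ± 0.28), Muc5ac (-3.76 ± 0.74), Igkv4-90 (-3.07 ± 0.39) and Scrg1 (-3.04 ± 0.59). Passing over V segments it added Ighg3 (2.76 ± 0.07), Spp1 (2.56 ± 0.26), the metalloprotease Mmp19 (2.13 ± 0.23) and Cxcl10 (1.98 ± 0.35) as positive and Prok2 (-2.14 ± 0.38) and Mrgpra2b (-1.75 ± 0.17) as negative. Median, mean and test differed in sign for the STING, co-stimulation, oxidative phosphorylation, unfolded protein, fibroblast and mast cell lists.

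The effect of each treatment was also compared across both backgrounds, in comparisons that share no library. Across 14182 genes, the log2 fold changes of cGAMP without and with the antibody had a Pearson r of -0.00157 (Spearman 0.00699), and 50.3% of genes had the same sign. Of the 355 genes called in both, 161 had the same direction and 194 the opposite. For the antibody without and with cGAMP the correlation was 0.226 (Spearman 0.365), with 65.5% of genes at the same sign, and 1355 of 1461 genes called in both had the same direction. Leaving out each library in turn gave jackknife standard errors of 0.0243 and 0.0441, and r for the antibody moved to 0.313 without V segments, 0.057 with no filter on low counts and 0.375 with the stricter filter. These correlations are across genes, which are not independent replicates.

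The 3 comparisons with IgG share their control libraries, which raises their overlap. cGAMP and anti-IL-35 shared 1001 higher and 253 lower calls, where independent lists of these sizes would share 208 and 47.1. cGAMP and the combination shared 1073 and 252 (independent 208 and 37.9), and anti-IL-35 and the combination 1790 and 538 (independent 348 and 99.2). Simulated unchanged groups against the same controls shared 0 calls over 20 simulations, and gave correlations of 0.498, 0.503 and 0.512 beside the observed 0.51, 0.543 and 0.638. The covariances were 0.163, 0.162 and 0.238, beside simulated values of 0.0462, 0.0469 and 0.0472. The 3 control libraries were not split between the comparisons, so part of the excess may come from them.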

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

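These results were picked out by the interaction test. The tests of V segments, neutrophil transcripts and NK receptors were chosen only after the results were seen, and the regroupings of libraries before.

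The interaction called 1475 genes. In 100 random assignments of the 12 libraries, the real one included, 1 called as many, and the next highest called 54. Such draws mix groups that differ. This raised the common biological coefficient of variation from 0.0958 to 0.172 or more in all other draws and so lowered their counts. The threshold set before was thus wrong, and the draws do not decide whether chance gave this count. Pairwise comparisons have 10 splits of 6 libraries, too few for a share under 0.05, and the other splits mix groups too. Real splits called 1834, 3542, 3288, 2102 and 829 genes and the highest others 0, 1, 0, 0 and 0, which decides nothing.

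Among V segments and other immunoglobulin genes, the interaction was 14.93 for Ighv1-43, 13.55 for Ighv1-56, 9.79 for Ighv1-36, 7.38 for Ighv1-84, 4.79 for Igkv14-130, -5.58 for Ighe, -5.03 for Igkv4-62, -3.07 for Igkv4-90 and 2.76 for Ighg3. The values of Ighv1-43 and Ighv1-56 depend on the prior count, since both had 0 counts with anti-IL-35. Ighv1-43 was at least 18.2-fold higher with the combination than with anti-IL-35, and 21.3-fold higher than with cGAMP (exact counting interval 5.59 to 180). The libraries of a group shared their V segment use, and 150 of 193 V segments ranged over 2-fold or more between group means. Reads shared between near-identical segments would keep r between groups as high as within them (0.967 or more), and the highest value of 0.861 argues against that as the whole cause.

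Libraries of a group made from one pool of cells or RNA may account for this, since V segments spread within groups no more than other genes of like mean (coefficients of variation of 10.8% and 10.9%, ratio 0.984). The headers of the deposited table give the libraries of a group a common stem. Independent animals are expected to differ in their B cell clones, but the labels state neither pools nor animals. If the libraries were made from one pool, no p-value here would measure differences between animals. A treatment effect on B cell clones stays open and was not tested.

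Neutrophil markers had an interaction median of -1.297, with Prok2 at -2.14 and Mrgpra2b at -1.75. B, T and dendritic cell sums fell in anti-IL-35 against IgG (4 other-cell lists called lower). This argues against a lower NK share raising all other cells alike. A share lowered by neutrophils alone stays open. RNA of neutrophils in the sorted fraction stays open. All 8 markers over 100 CPM with IgG were called higher with anti-IL-35, but so was the whole list, so this decides nothing. Neutrophil infiltration of the tumour cannot be told from carry-over in the sort, as no cell counts before sorting were given (ratio of summed CPM 4.34).

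NK receptor transcripts were lower with the combination than with cGAMP, and their interaction values were -0.375 for Klrk1, -0.187 for Ncr1, whose call ended under 12 settings and turned under 1 more, and -0.23 for the median of the activating list. Dilution by RNA of other cells stays open, as 16 receptors with a median of -0.35 (-0.64 to -0.14) overlapped 10 other NK transcripts with one of -0.20 (-0.49 to 0.08, difference of medians 0.153), and both sets were chosen after the fall was seen. The permutation p of that difference was 0.00767, and 13 of the 16 and 4 of the 10 were called lower, which decides nothing for sets formed in this way. The choice between TMM and the other planned scalings is argued against, since the median of the receptors was -0.36 with RLE and -0.39 with library totals alone (-0.391). A treatment effect on NK cells stays open as a hypothesis.

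Other interaction values were -0.235 for Prf1, -0.51 for Eomes, -0.97 for Ebi3 and 2.66 for Il12a. Further genes were Muc5ac at -3.76, Scrg1 at -3.04, Arg1 at 2.79, Spp1 at 2.56, Mmp19 at 2.13 and Cxcl10 at 1.98. List medians were -0.11 for NK maturation, 0.14 for interferon-gamma response and MHC class I, -0.13 for glycolysis, -0.12 for immediate-early and heat-shock, -0.18 for migration, 0.60 for B cell, 0.22 for macrophage, 0.49 for dendritic cell and -0.74 for tumour and ductal genes.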

How the results depend on the processing

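NK receptor scaling and the fit without immunoglobulin and other-cell-list genes were chosen after seeing the data. The cause of each change named here was not tested unless stated.

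Counts of called genes stayed within 1.5 times the reported count under RLE, library totals alone, DESeq2, both filters, the fit of only the groups compared, the replicate block and every left-out library. Counts for the combination against cGAMP and anti-IL-35 and for the interaction were 7138, 2952 and 3835 with NK receptor scaling. The combination against anti-IL-35 gave 529 calls without immunoglobulin and other-cell-list genes, a fit that tests fewer genes.

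Fry called 20, 21, 20, 27, 16 and 20 lists in the order of the comparisons, as it does not compare a list with other genes. With an estimated correlation the combination against IgG kept 7 lists. The replicate block changed no list call. Under NK receptor scaling 4 lists turned: in the combination against cGAMP, NK maturation (adjusted p = 0.879), oxidative phosphorylation (0.879) and B cell markers (0.825), and in the interaction NK maturation (0.956).

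Prf1 in anti-IL-35 against IgG stood at -0.002 with library totals alone. Other genes turned with NK receptor scaling, called or not. In the combination against IgG these were Eomes (0.053), Gzmb (0.201) and Klrk1 (0.017). Against cGAMP they were Ctsw (0.046), Eomes (0.048), Gzma (0.11), Il12rb2 (0.277), Il27ra (0.267), Il6st (0.257), Klrb1c (0.007), Klrk1 (0.006), Ms4a1 (0.018), Ncr1 (0.049), Prf1 (0.248), Tbx21 (0.261), Tmem173 (0.196) and Trbc2 (0.002). Against anti-IL-35 they were Ncr1 (0.042) and S100a9 (0.014), and in the interaction Ncr1 (0.153) and Prf1 (0.102).

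The correlation of the cGAMP effects was 0.0335 without immunoglobulin and other-cell-list genes. That of the antibody effects was 0.057 with no filter on low counts, 0.375 with the stricter filter and 0.317 without immunoglobulin and other-cell-list genes. It ran from 0.181 without cGAMP replicate 1 to 0.225 without IgG control replicate 2.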

Other observations

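Erythroid and platelet markers summed to 513 ± 7.0 CPM with IgG, 1089 ± 25.0 with cGAMP, 611 ± 13 with anti-IL-35 and 977 ± 18.6 with the combination (SD, n = 3).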
